A study of Drosophila melanogaster with 3 samples.

How the data were processed

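Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed, per the labels, on whole mixed-sex Drosophila melanogaster embryos aged 0 to 24 h from a transgenic line that expresses Schnurri (shn) with a C-terminal GFP tag. Chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The 3 samples are biological replicates of 1 group, numbered 1 to 3 as in the labels, so the design gives the agreement between replicates and a description of the bound sites, with no contrast between conditions. A control was used by the authors in calling peaks, per the notes deposited with the lists, and was not analysed here.

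The authors deposited peak lists on 2 builds, dm6 and dm3. For each replicate, and for the 3 replicates pooled, the authors' list holds peaks and background kept as input for the irreproducible discovery rate (IDR) procedure, which keeps peaks whose ranks repeat between replicates. A further list holds the authors' optimal IDR-thresholded peaks, called the reproducible peaks here. Each peak of the deposited lists has a signal value and a −log10 q value given by the authors' peak caller, and a summit position. The peak caller and the IDR threshold are not given in the sources used here. The signal values are the authors' own per peak, and they were used only to rank, filter or describe peaks within one list; where a peak is followed across replicates its rank is given, since the 3 replicate lists hold 30000 peaks each. No read counts were used, so the sequencing depth of each sample is unknown. Intervals on shares of peaks or genes therefore cover counting error over peaks or genes only, which are not replicates.

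Peaks were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. Coordinates are on dm6 (Release 6), 1-based, with chromosome arms 2L, 2R, 3L, 3R, 4 and X. Genes and transcription start sites (TSSs) came from the Ensembl release 115 annotation of BDGP 6.54, limited to 13945 protein-coding genes with 19607 distinct TSSs on these 6 arms, and sequence came from the Release 6 assembly. All dm6 peaks lay within the arm lengths of that assembly. The dm3 lists were compared only with each other.

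A peak matched another when they overlapped by at least 1 bp. Each replicate list was ranked by signal and reduced to its top 3586 peaks, the number in the reproducible list. Agreement was measured as the share of reproducible peaks found in the top lists of all 3 replicates, the mean overlap of the top lists over the 3 pairs, and Spearman's correlation of signal across matched peaks, for which no p is given because peaks are not independent. Random expectation came from 100 random placements of the same intervals on the same arms; these ignore mappability, so the pooled peaks outside the reproducible list served as a further comparison. A summit within 1 kb of a TSS was called promoter-proximal and any other distal. Annotation at the summit was assigned in the order 5' UTR, coding sequence, 3' UTR, remaining gene body and intergenic, using every protein-coding gene, so that a summit in a gene body is not always in the gene named. Wilson 95% intervals were used for shares.

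For 19 gene lists, the share of genes with a reproducible summit within 1 kb of any TSS was compared with all other protein-coding genes by two-sided Fisher's exact test (scipy 1.17.1), with Benjamini-Hochberg adjustment over the 19 lists. The lists were Dpp/BMP pathway components, BMP-responsive dorsal patterning genes, genes reported to be silenced by Schnurri with Mad and Medea, the Wnt, Hedgehog, Notch, EGFR and JAK/STAT pathways, gap and pair-rule genes, Hox genes, tracheal, neural, mesoderm and heart, muscle structural, amnioserosa and dorsal closure, germline and ecdysone response genes, cytoplasmic ribosomal protein genes, and chemosensory receptor genes. For 6 listed symbols the annotation uses another name, and all listed symbols were found. For 14 sequence motifs, the share of reproducible peaks with a match within 100 bp of the summit was compared with windows of the same length centred 1000 bp to either side, leaving out flanks near another summit, by two-sided Fisher's exact test adjusted over the 14 motifs. Each motif was also compared with 20 column-shuffled versions of itself. A test over genes stratified by their number of TSSs (1, 2, or 3 and more) used the Mantel-Haenszel estimate of statsmodels 0.14.6. The number of pooled peaks in the 100 kb centred on shn was ranked among the 1323 windows of 100 kb on the 5 large arms.

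The lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names the gene with the nearest TSS to each of the 15 peaks of highest signal that lie in the top lists of all 3 replicates; shn, brk, Dad, dpp and pnr in any case; up to 4 members with the strongest peaks of each list past the 0.05 adjusted threshold, and up to 2 of each other list. Alternatives were TSS windows of 500 bp and 5 kb, peaks at or above the median signal only (1793 peaks), other top-list sizes and overlap rules, the dm3 lists, stratification by TSS number, motif windows of 50 and 250 bp, flanks at 2000 bp, distal peaks only, and leaving out each replicate in turn. Leaving out a replicate meant taking the top 3586 peaks of one remaining replicate that overlapped those of the other. A further 10 gene groups, a search of 8-mers at summits, tests within shn, and 3 alternatives that leave out shn were added after results had been seen. A comparison of DRE with promoters without a peak was added after the motif results, with its prediction written before its own value was seen. Its windows were centred 76 bp upstream of each TSS, the median position of proximal summits.

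The code was tested on simulated data. Of peaks planted in a second list, 100% were found, and 4.26% of unplanted peaks matched by chance. With peaks at 70% of the members of a list, the ribosomal protein list of 89 genes was called in 100% of 100 simulated sets and the EGFR list of 19 genes in 96%. Lists with no effect were called in 0.267% of tests. In these simulated sets, genes outside the planted lists all had the same chance of a peak, whatever their number of TSSs. False calls that come from TSS number or shared promoters were therefore not measured. DRE planted in 5% of windows was called in 100% of 20 sets, and motifs not planted in 0.769% of tests.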

Results

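Binding of Schnurri (Shn), the zinc finger protein that acts with the Smad proteins Mad and Medea downstream of the BMP ligand Dpp, was mapped in 0 to 24 h whole embryos by ChIP-seq against a GFP tag on the protein. The 3 biological replicates form 1 group, and each replicate list holds 30000 ranked peaks and background regions. The authors' reproducible list holds 3586 peaks on dm6, with signal from 91.6 to 2020 and a median of 142, and all 3586 are the peaks of highest signal in the pooled list of 30000. The lists differed in how many regions passed a −log10 q of 2, with 2385 in replicate 1, 5289 in replicate 2 and 7213 in replicate 3. Read depth is unknown.

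The 15 peaks of highest pooled signal were in the top lists of all 3 replicates. The pooled signal draws on these same replicates, so this is no separate evidence of agreement. The peaks ranked 1 to 15 lay nearest to CG14100, cbt, Ugalt, Chro, Lk6, px, CG1888, CG4004, Shc, PNPase, Pal1, Sox14, CG31145, Atf3 and CG11050, and none ranked below 32 of 30000 in any replicate. At 12 of the 15 the summit lay within 1 kb of the TSS. The first peak, with a signal of 2020, had its summit at position 19590614 of 3L, 90 bp upstream of CG14100, and ranked 1 in every replicate. The second lay 1388 bp upstream of cbt (cabut, a zinc finger transcription factor) at position 481076 of 2L, within the body of ush, and ranked 3, 2 and 2 in replicates 1, 2 and 3. Chro, which encodes a chromodomain protein of interbands, had its peak in the 5' UTR at position 22878884 of 3L and ranked 5, 5 and 6. The summit at Sox14, a gene induced by ecdysone, lay 260 bp upstream at position 23978541 of 2R. That at Atf3, a bZIP transcription factor, lay 218 bp upstream at position 1275502 of X. At 5 of the 15 peaks another gene also had a TSS within 1 kb of the summit, as with eIF2Bbeta beside Ugalt and Ssl1 beside Chro.

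Below the strongest peaks the replicates differed more. The top lists of replicates 1, 2 and 3 held 74.2%, 85.0% and 78.1% of the reproducible peaks. In all 3 were 1930 of 3586 (53.8%, 95% interval 52.2 to 55.4), against a mean of 0.931% for random placements. Because the reproducible list was drawn from these same replicates, a share above random placement was built in and is no evidence of agreement. Top lists overlapped by 69.7% between replicates 1 and 2, 58.5% between 1 and 3 and 70.1% between 2 and 3 (mean 66.1 ± 6.63, SD over 3 pairs, which are not independent). Spearman's correlation of signal across matched peaks was 0.715, 0.497 and 0.634 for the same pairs (mean 0.615 ± 0.110, SD, 3 pairs). Replicate 1 had no match at all for 332 reproducible peaks, while replicates 2 and 3 lacked 6 and 10. Signal and the GC content of peaks were correlated at −0.203 in replicate 1, −0.125 in replicate 2 and 0.108 in replicate 3, across peaks. With GC held constant the correlation between replicates 1 and 3 was 0.531, and it was 0.515 within promoter-proximal and 0.462 within distal peaks, the lowest of the 3 pairs in each case.

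Most Schnurri peaks lay near promoters, more often upstream than downstream of the TSS. Of the reproducible summits, 65.1% (63.6 to 66.7) were within 1 kb of a TSS, against a mean of 20.3% and a highest value of 22.3% in 100 random placements (one-sided permutation p = 0.0099, the smallest they can give) and 36.0% of the remaining pooled peaks. With the reproducible peaks split by signal into 4 classes, the share was 71.1% in the class of highest signal and 59.5% in the lowest. The median distance to a TSS was 305.5 bp, and 75.2% of proximal summits were on the upstream side. Coding sequence held 0.948% of reproducible summits, against 16.8% by random placement and 26.9% of the remaining pooled peaks. The 5' UTR held 13.0%, against 3.34% by random placement and 7.93% of the remaining pooled peaks. Median signal at promoter-proximal peaks was 1.14 ± 0.0995 times that at distal peaks (SD, n = 3), above 1 in all 3 replicates (two-sided exact sign-flip test, p = 0.25, the smallest that 3 replicates allow). Chromosome X held 18.2% (16.9 to 19.4) of the peaks and 17.6% of the length of the arms, and arm 4 held 14 peaks.

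**Figure D1:**
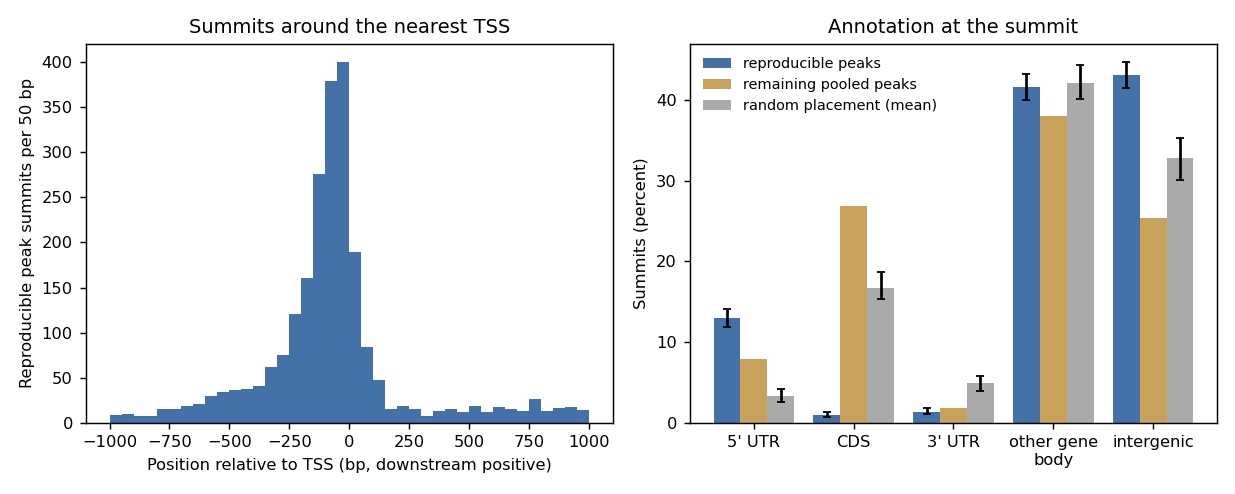
Left, number of reproducible summits per 50 bp by position from the nearest TSS in bp, and right, percent of summits by annotation for reproducible peaks (error bars, 95% interval), remaining pooled peaks and random placements (mean, bars from lowest to highest of 100). Summits within 1 kb are densest just upstream of the TSS, and coding sequence holds 0.948% of reproducible but 26.9% of remaining pooled summits.

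Among genes of the Dpp pathway, the strongest promoter peak was at brk (brinker, FBgn0024250), which encodes a repressor of Dpp target genes and is itself repressed through Schnurri. Its summit at position 7307744 of X lay 195 bp upstream of the TSS (gene 7307939 to 7311132), within the span of CG1677, a gene on the other strand. It had a pooled signal of 699 and ranked 55 among the reproducible peaks, and it was in the top lists of all 3 replicates, at ranks 1731, 61 and 12. The peak 228 bp upstream of a TSS of magu, a secreted BMP modulator, ranked 110. At dpp (FBgn0000490) a summit 44 bp upstream of an internal TSS, at position 2451185 of 2L, ranked 3017 and was in the top lists of 2 replicates, with rank 20358 in replicate 1. The inhibitory Smad gene Dad had no reproducible summit within 1 kb of a TSS; its nearest, 10253 bp away at position 17065150 of 3R, lay in the gene body outside coding sequence and UTRs and ranked 511. The summit nearest to a TSS of pnr (pannier) was 14966 bp from that TSS, in intergenic sequence at position 16049552 of 3R. In all, 9 of 24 Dpp/BMP pathway genes had a promoter peak (37.5% against 21.1% of other genes), an odds ratio of 2.24 (0.864 to 5.47) that did not pass (Fisher's exact test, adjusted p = 0.283). Without replicate 2 the odds ratio was 3.26 (Fisher's exact test, adjusted p = 0.0471), and without replicate 3 it was 1.42. BMP-responsive dorsal patterning genes had peaks at 4 of 20 (odds ratio 0.932, Fisher's exact test, adjusted p = 1), led by ush and Btk, and the odds ratio was 0.619 without replicate 1 and 0.598 without replicate 3. Of the genes reported to be silenced by Schnurri with Mad and Medea, 1 of 3 had a peak, which was brk (odds ratio 1.86, Fisher's exact test, adjusted p = 0.805). That odds ratio was 3.26 without replicate 2, 3.23 with a 5 kb window and 3.69 with peaks at or above the median signal, and none of these passed.

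The tagged gene itself carried a dense run of peaks. In shn (FBgn0003396, 2R from 11159086 to 11217394, plus strand) 25 reproducible summits lay within the gene, 7 of them within 1 kb of a TSS, and 18, 22 and 23 of the 25 were in the top lists of replicates 1, 2 and 3. The best rank among all 25 summits in the gene was 160. The strongest peak near a TSS of shn was 663 bp downstream, in the 5' UTR at position 11198939, and ranked 471, with no matching peak in replicate 1. The 100 kb centred on shn held 27 reproducible peaks, against a median of 2 and a highest of 16 in windows clear of it. In the pooled list the same window held 69 peaks, the 99.9th percentile of 1323 windows (median 23, highest clear of shn 77), and the percentiles in replicates 1 to 3 were 100, 99.9 and 99.7. Because the line carries a tagged shn, an altered copy number of this region cannot be separated from binding by these counts alone.

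**Figure D2:**
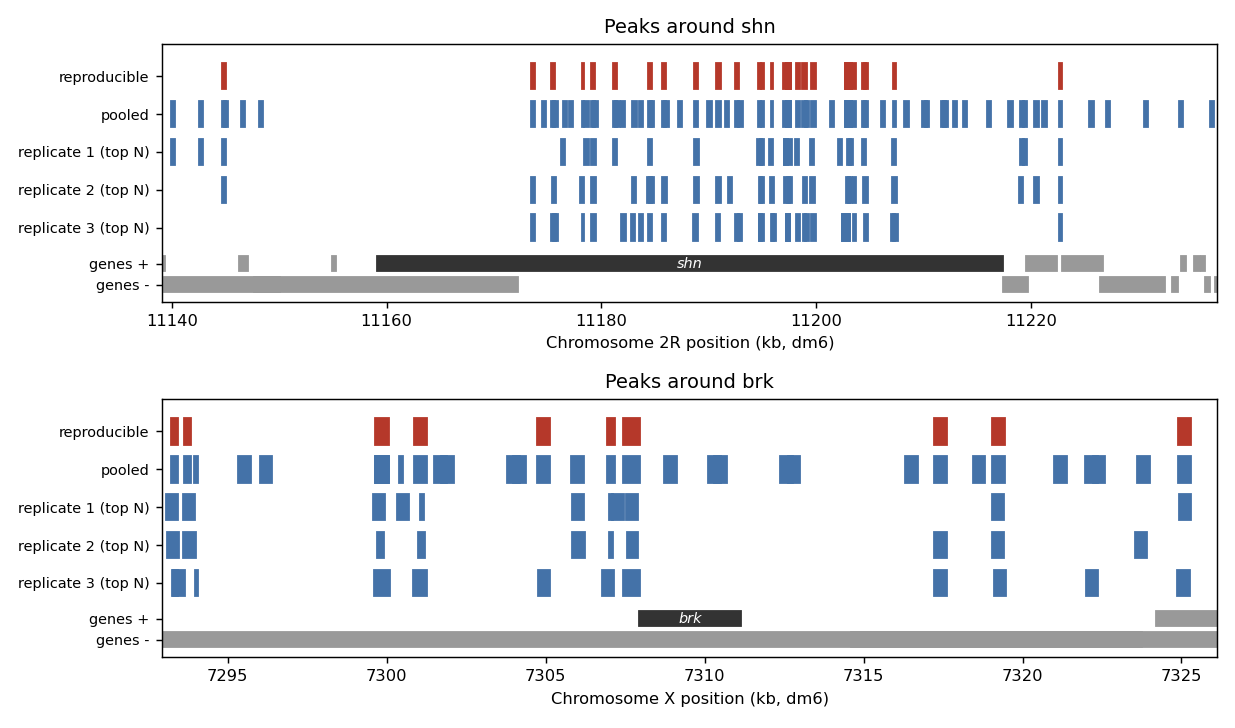
Peaks around shn (top, chromosome 2R) and brk (bottom, chromosome X) by dm6 position in kb, for the reproducible list (red), the pooled list and the top 3586 peaks of each replicate (blue), with genes drawn below by strand and the named gene dark. The 25 reproducible summits within shn lie in the middle of the gene, and the brk summit lies 195 bp upstream of its TSS.

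Cytoplasmic ribosomal protein genes often had a promoter peak. Of 89, 62 had a promoter peak (69.7% against 20.8% of other genes, odds ratio 8.72, 5.46 to 14.3, adjusted p = 1.66e-21, Fisher's exact test over 19 lists). RpS27, RpL7, RpL23A and RpL14 carried the strongest peaks, at ranks 43, 47, 85 and 126, with summits 19 bp upstream, 21 bp downstream, 113 bp upstream and 30 bp upstream of the TSS. Each was in the top lists of all 3 replicates, but at lower ranks in replicate 1 (153, 193, 253 and 703) than in replicate 3 (28, 19, 47 and 55). RpS27, RpL7 and RpL14 share their promoter region with Nup37, Ripalpha and Nelf-E. The odds ratio of the list was 5.63 with a 5 kb window, 8.79 without replicate 1, 5.66 without replicate 2 and 4.67 without replicate 3. Chemosensory receptor genes, which act in sensory neurons, were the opposite, with peaks at 2 of 179 (1.12% against 21.4%, odds ratio 0.0415, 0.00498 to 0.152, Fisher's exact test, adjusted p = 5.03e-15). The 2 genes, Or88a and Ir60e, have another gene (CG12402 and CG13585) with a TSS within 1 kb of the summit. With a 500 bp or 5 kb window the odds ratio of the chemosensory list was 0.0244 or 0.223.

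The EGFR pathway and the genes of the amnioserosa and dorsal closure were also past the threshold. EGFR pathway genes had peaks at 11 of 19 (57.9%, odds ratio 5.14, 1.88 to 14.7, Fisher's exact test, adjusted p = 0.00324), led by the ligand gene spi at rank 109, Raf at 124, the repressor gene aop at 505 and Ras85D at 645, each in the top lists of all 3 replicates. With only the 1793 peaks at or above the median signal the call was lost (odds ratio 3.41, Fisher's exact test, adjusted p = 0.0935). Genes of the amnioserosa and dorsal closure had peaks at 8 of 16 (odds ratio 3.74, 1.22 to 11.4, Fisher's exact test, adjusted p = 0.0470), led by jar at rank 805, ush at 901, pyd at 1104 and puc, the JNK phosphatase gene, at 1208. The puc peak was in the top lists of 2 replicates, with rank 12225 in replicate 1. The call for the amnioserosa and dorsal closure list was lost with genes stratified by their number of TSSs, where the odds ratio was 2.02. By Fisher's exact test it was also lost with a 500 bp window (odds ratio 3.44, adjusted p = 0.0836), with peaks at or above the median signal (4.44, adjusted p = 0.0503) and without replicate 2 (3.92, adjusted p = 0.0511).

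The other lists did not pass. Ecdysone response genes had peaks at 5 of 12 (odds ratio 2.67, Fisher's exact test, adjusted p = 0.464), led by Eip75B at rank 164 and E23 at 316, and passed only with a 5 kb window (odds ratio 8.09, adjusted p = 0.0119), while over TSS strata the odds ratio was 1.16. The Notch pathway and E(spl) complex had 6 of 19 (1.72, 0.627), with E(spl)m3-HLH and E(spl)m7-HLH first. Germline genes had 4 of 13 (1.66, 0.805), including bgcn and orb, and an odds ratio of 1.01 without replicate 1. The JAK/STAT pathway had 3 of 10 (1.60, 0.805), with Ptp61F and Stat92E. Tracheal genes had 4 of 14 (1.49, 0.805), with bs and bnl. Wnt pathway genes had 5 of 20 (1.24, 0.805), with sgg at rank 115 and Wnt6. Hedgehog pathway genes had 3 of 12 (1.24, 0.919), with rdx at rank 140 and smo. The direction of several of these depended on the setting. With 1 replicate left out the odds ratio ran from 0.766 to 1.44 for Notch, 0.414 to 2.23 for tracheal and 0.723 to 1.39 for Wnt genes, and with peaks at or above the median signal it was 0.409 for Notch, 0.567 for tracheal, 0.670 for Hedgehog and 0.351 for JAK/STAT genes. The JAK/STAT value came from 0 of 10 genes, with 0.5 added to each cell. With a 5 kb window the odds ratio was 2.77 for Notch, 0.897 for tracheal and 2.43 for Wnt genes. Below 1 were the mesoderm and heart genes and the muscle structural genes, each with 3 of 17 (0.799, 1), where srp, how, sls and TpnC47D had peaks. With 1 replicate left out these ran from 0.186 to 0.348 and from 0.336 to 0.868, over TSS strata they were 0.528 and 0.486, and none passed. The value of 0.186, without replicate 2, came from 0 of 17 genes, with 0.5 added to each cell. With a 5 kb window the direction of the mesoderm and heart genes turned (1.82), while that of the muscle genes did not (0.673). Neural determinants had 3 of 19 (0.699, 0.927), with elav and scrt, and an odds ratio of 0.409 with peaks at or above the median signal. Gap and pair-rule genes had 2 of 17 (0.497, 0.805), which were bcd and hry. The named peaks of Stat92E, bnl, srp, how and hry were each in the top lists of 2 replicates only, and that of TpnC47D in 1. None of 8 Hox genes had a peak (odds ratio 0.219 with 0.5 added to each cell, upper bound 2.18, Fisher's exact test, adjusted p = 0.588). Values in brackets are odds ratio and adjusted p.

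**Figure D3:**
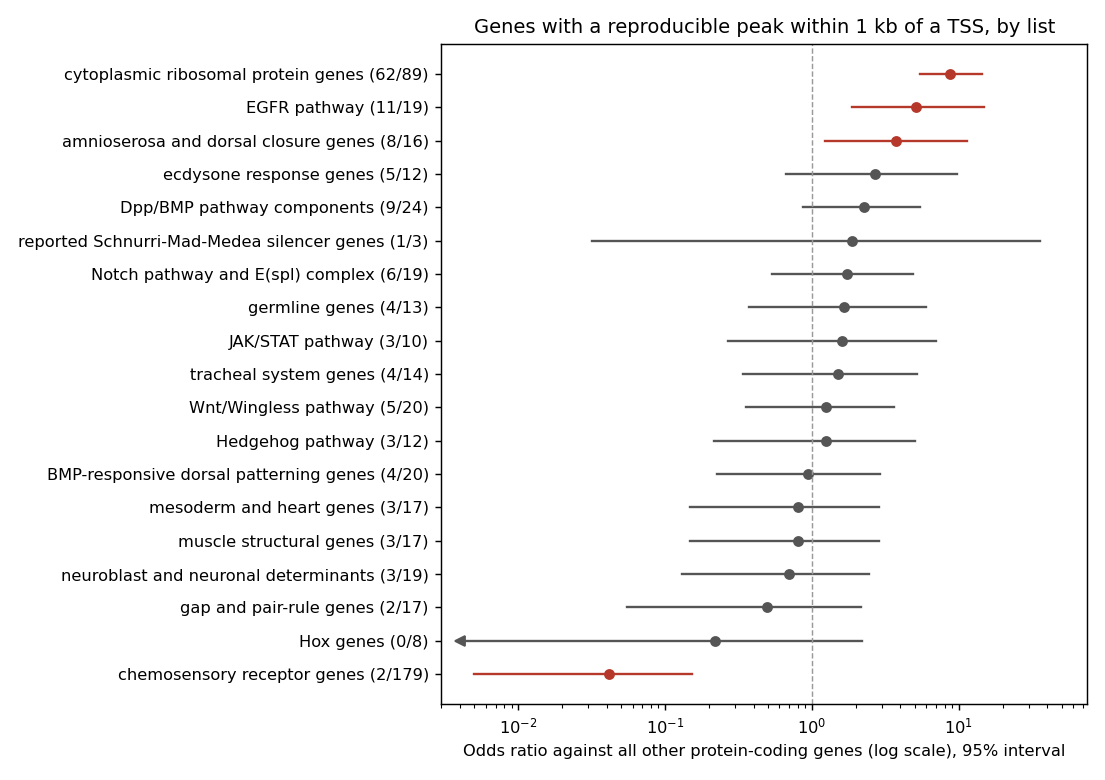
Odds ratio (log scale) of having a reproducible peak within 1 kb of a TSS for each of 19 gene lists against all other protein-coding genes, with 95% intervals genes with a peak over genes measured, lists past the 0.05 adjusted threshold in red, and an arrow where an interval runs off the axis. Ribosomal protein genes lie at 8.72 and chemosensory receptor genes at 0.0415.

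Within 100 bp of the summits, the promoter elements DRE and M1BP motif 1 had the highest odds ratios of the 14 motifs, and the element reported for Schnurri with Mad and Medea did not pass. The DRE (TATCGATA), bound by DREF, was within 100 bp of 5.19% of summits and in 0.483% of flanking windows (odds ratio 11.3, 7.74 to 16.9, Fisher's exact test, adjusted p = 9.87e-54, highest of 20 shuffled versions 4.31). M1BP motif 1 was at 1.53% against 0.176% (8.86, 4.68 to 18.2, Fisher's exact test, adjusted p = 7.89e-15), but 1 of its shuffled versions reached 9.54. Its odds ratio was 3.90 with peaks at or above the median signal, 4.32 without replicate 2 and 4.95 without replicate 3. That of DRE was 7.01 with a 250 bp window. In distal peaks the odds ratios were 0.881 for DRE and 0.484 for M1BP motif 1, and neither passed. At promoters without a peak, DRE was in 6.24% of windows centred 76 bp upstream of the TSS, against 7.75% of windows at promoter-proximal summits, and M1BP motif 1 was in 2.60% against 2.27%. The silencer element was at 5 of 3586 summits and in 6 of 6837 flanks (odds ratio 1.59, 0.383 to 6.26, Fisher's exact test, adjusted p = 0.672). Its odds ratio was 2.31, 0.643 and 0.482 without replicates 1, 2 and 3, 0.967 with peaks at or above the median signal, 2.60 with a 50 bp window and 2.91 in distal peaks, so its direction was not stable. The Dpp activating element was at 12 summits and in 5 flanks (odds ratio 4.59, Fisher's exact test, adjusted p = 0.0125, highest shuffled version 3.82). Within 50 bp it was at 7 summits and in 1 flank (13.7, 1.76 to 616), where DRE had 9.65 and M1BP motif 1 had 11.4. The call for the Dpp activating element was lost with peaks at or above the median signal, in distal peaks and without any one replicate, where the odds ratios ran from 0.643 to 3.09. The GC-rich Mad site was less frequent at summits than in flanks (2.01% against 2.94%, odds ratio 0.676, Fisher's exact test, adjusted p = 0.0125), but its shuffled versions ran from 0.237 to 1.24 with a median of 0.631. Among the remaining pooled peaks, 5.27% had a match to the Mad site. These differ in location, with 26.9% of their summits in coding sequence against 0.948% of reproducible summits. The share was not adjusted for this. The call for the Mad site was lost with a 250 bp window (0.971), with peaks at or above the median signal (0.611), in distal peaks (0.757) and without replicate 1 (0.668). The GAGA repeat (1.31, Fisher's exact test, adjusted p = 0.0175) was below 1 in distal peaks (0.896), in peaks at or above the median signal (0.873), without replicate 2 (0.792) or 3 (0.782), and with a 50 bp window (0.915), but was 2.13 with a 250 bp window and 1.62 with flanks at 2000 bp. The E-box CACATG (0.807, Fisher's exact test, adjusted p = 0.0125) lay within its shuffled versions (0.581 to 2.95) and was lost without any one replicate and in most other settings. No other motif passed with these windows and flanks. The odds ratio was 1.13 for the E-box CAGCTG, 1.14 for the Tinman site, 1.02 for the Su(H) site and 0.953 for the Grainyhead site. It was 0.913 for the NF-kB-like site, 0.881 for the Zelda site and 0.619 for the TCF site. All of these except the Tinman and TCF sites crossed 1 in at least 1 other setting. With a 250 bp window CAGCTG (1.15, Fisher's exact test, adjusted p = 0.0172) and the TCF site (0.602, adjusted p = 0.0198) passed, as did the Zelda site with flanks at 2000 bp (0.732, adjusted p = 0.0423). The Grainyhead site had 0.385 without replicate 2, 0.593 without replicate 3 and 0.483 with peaks at or above the median signal.

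**Figure D4:**
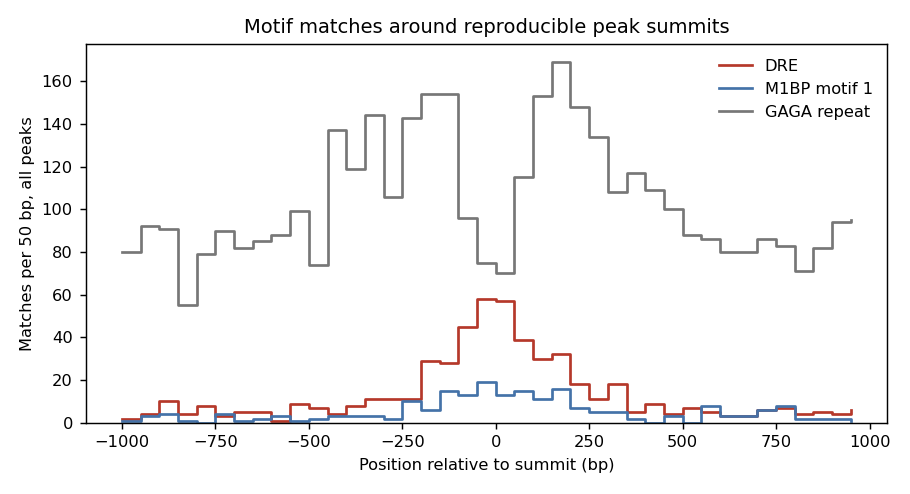
Matches to DRE, M1BP motif 1 and the GAGA repeat per 50 bp, summed over all 3586 reproducible peaks, by position from the summit in bp. DRE and M1BP motif 1 are densest around the summit, while the GAGA repeat is densest to either side of it.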

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

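The settings that leave out shn were chosen after seeing the data, and the others before. Of the alternative values of the main results, 222 were counted as kept. These kept their direction and side of the threshold, or without a test stayed within the spread, the 95% interval or, for the peak count, 1.5 times the value. The share within 1 kb of a TSS was counted as kept where it stayed above random placement. Its 67.4% without replicate 2 and 68.5% at or above the median signal lay outside its 95% interval. A further 33 reversed, of which 8 also lost a call, 21 lost a call without reversing, 5 gained one and 16 moved. Ribosomal protein genes stayed between 4.67 and 9.32, and chemosensory receptor genes between 0.0244 and 0.223. The share within 1 kb of a TSS became 55.9% at 500 bp and 86.1% at 5 kb. Without the peaks inside shn, 3561 peaks were left, 65.4% of them near a TSS, and without shn in its list the Dpp pathway had an odds ratio of 1.99. The dm3 lists held 3575 reproducible peaks, and the measures of agreement and the X share stayed within the spread or interval. No paired analysis was possible because the samples form 1 group. Depth is unknown, so what depth limits could not be examined, and for the changes given here the cause was not tested.

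The share of reproducible peaks in all top lists was 17.1% with the top 1000 peaks, 76.5% with the top 7172, 40.7% with 50% reciprocal overlap, 47.4% with summits within 100 bp and 57.6 to 68.0% with 1 replicate left out. With the top 1000 peaks the size of the lists itself caps the share. The number of reproducible peaks was 1793 at or above the median signal, which follows from the definition of a median, and 2064 to 2439 were held by the top lists of 2 replicates. Pairwise overlap was 56.1% with the top 7172 peaks, 59.0% by summits and 58.5 to 70.1% over single pairs, where Spearman's correlation was 0.497 to 0.715. The X share was 18.0 to 19.6% with 1 replicate left out.

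Odds ratios of gene lists changed as follows. With a 500 bp window they were 0.882 for Hedgehog and 3.44 for amnioserosa genes. With 5 kb they were 0.897 for tracheal, 1.82 for mesoderm and 8.09 for ecdysone genes. With peaks at or above the median signal they were 0.819 for Wnt, 0.670 for Hedgehog, 0.409 for Notch, 3.41 for EGFR, 0.351 for JAK/STAT, 0.567 for tracheal and 4.44 for amnioserosa genes. Over TSS strata they were 0.989 for Wnt and 2.02 for amnioserosa genes. With 1 replicate left out they ran from 1.42 to 3.26 for Dpp, 0.723 to 1.39 for Wnt, 0.766 to 1.44 for Notch, 0.414 to 2.23 for tracheal, 0.186 to 0.348 for mesoderm, 0.336 to 0.868 for muscle and 3.92 to 4.34 for amnioserosa genes.

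Among motifs, a 50 bp window gave 1.02 for the NF-kB-like site, 0.915 for GAGA and 0.929 for Su(H). A 250 bp window gave 0.971 for the Mad site, 1.19 for Grainyhead, 1.15 for CAGCTG, 0.919 for CACATG and 0.602 for TCF, and CAGCTG and TCF then passed. Flanks at 2000 bp gave 0.732 for Zelda, which then passed, and 0.852 for CACATG. Peaks at or above the median signal gave 0.967 for the silencer element, 0.611 for the Mad site, 2.58 for the Dpp activating element, 0.873 for GAGA, 0.826 for CACATG and 0.882 for Su(H). Distal peaks gave 0.757 for the Mad site, 2.91 for the Dpp activating element, 1.44 for Zelda, 0.896 for GAGA, 0.881 for DRE, 0.484 for M1BP motif 1, 0.808 for CAGCTG and 0.763 for CACATG. With 1 replicate left out the ranges were 0.482 to 2.31 for the silencer element, 0.485 to 0.668 for the Mad site, 0.643 to 3.09 for the Dpp activating element, 0.782 to 1.23 for GAGA, 0.961 to 1.14 for CAGCTG, 0.845 to 0.893 for CACATG and 0.851 to 1.10 for Su(H).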

Other observations

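The tests of 8-mers, within shn and with 1 TSS per gene, and all 10 further gene groups, were chosen after the results had been seen, as was the use of the planned shuffled motifs and TSS strata to test an explanation, and the arms held out for 8-mers had been looked at before. The tests of DRE at promoters without a peak and of the signal rank of ribosomal protein genes were stated before their values were seen. So was the test of DRE in distal peaks, but the rule for reading it was changed after its value was seen. Among 10 further gene groups tested together, mitochondrial ribosomal protein genes had promoter peaks at 27 of 73 (odds ratio 2.20, Fisher's exact test, adjusted p = 0.00541), with mRpL41, mRpS10 and mRpS23 at ranks 17, 20 and 23. Each of these summits also lay within 1 kb of a TSS of another gene (CG8079, Art3 and CenG1A). Polycomb and Trithorax group genes had 9 of 20 (3.06, Fisher's exact test, adjusted p = 0.0403), led by ph-p at rank 18 and including E(z), Psc and brm. Genes of chromatin architecture and promoter factors had 7 of 15 (3.27, Fisher's exact test, adjusted p = 0.0403), among them Chro, Trl, Dref, M1BP and BEAF-32. Chro, at rank 4, was already among the leading peaks when the group was chosen, so the p of the group is no independent support. For this group 16 symbols were listed and 15 were found in the annotation. With genes stratified by number of TSSs, where a Mantel-Haenszel test replaced Fisher's, both of these calls were lost. Their odds ratios were then 2.75 and 3.38, close to the 3.06 and 3.27 without strata. The loss therefore does not show that TSS number accounts for them. The call of the mitochondrial ribosomal proteins held (2.86). Proteasome subunits (8 of 48, 0.745), translation initiation factors (10 of 44, 1.10) and aminoacyl-tRNA synthetases (9 of 32, 1.46) did not pass.

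Other groups had few promoter peaks, with 1 of 114 cuticle protein genes (odds ratio 0.0327, Fisher's exact test, adjusted p = 7.7e-10), 2 of 85 cytochrome P450 genes (0.0892, adjusted p = 3.67e-06) and 1 of 51 odorant-binding protein genes (0.0743, adjusted p = 0.00037). Jonah and trypsin proteases had 1 of 27 (0.143, Fisher's exact test, adjusted p = 0.0428), a call lost over TSS strata (odds ratio 0.201).

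DRE and a second family of sequences lay at the summits, and no biological explanation was tested because the design has 1 group. Shuffled versions of DRE reached an odds ratio of at most 4.31 against the real 11.3 (lower bound 7.74), which argues against base composition alone, while promoter location may account for most of it, since the odds ratio in distal peaks was 0.881 (0.239 to 2.76). Against promoters without a peak it was 1.26 (1.06 to 1.49), which by the test as stated argues against an equal frequency there, though the difference is small. With 1 TSS per gene, added after that value was seen, it was 1.16 (0.972 to 1.37), as the share without a peak rose from 6.24 to 6.76%. That interval reaches 1, so by the same rule an equal frequency may hold, and the comparison does not decide. Peak windows were also centred on summits, where DRE was densest, and the others at a fixed position. The rule for reading the distal test was changed after its value was seen. The interval of that test is wide, so some enrichment of DRE in distal peaks is not excluded. Of 2207 8-mers ranked on 2L, 2R and 4, the 10 leading ones had a median odds ratio of 6.78 on 3L, 3R and X (3.41 to 10.4 over the 10), which argues against chance among 8-mers. They include DRE itself, already enriched over all arms, and several overlap (as ACTATCGA and AACTATCG do), so they are not 10 separate results. In distal peaks of 3L, 3R and X the 4 with CACTG had 4.90 (3.20 to 7.62, carried by 3 of them), which argues against promoter location alone. The other 6 had 0.843 (0.444 to 1.54), as promoter location would give.

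Peaks at ribosomal protein genes were frequent and strong. The number of TSSs per gene did not account for the frequency, as the odds ratio over TSS strata was 7.15. Their peaks stood at a median signal percentile of 68.8 among all genes with a promoter peak (two-sided permutation p = 0.00177). That is what would be seen if signal followed highly transcribed promoters whatever protein was precipitated, so this explanation may hold and stays open. No control precipitation was analysed here that could separate it from binding by Schnurri.

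The density of peaks within shn may reflect extra copies of the tagged gene or binding of Schnurri to its own locus, and these cannot be told apart here. An even background from extra copies would place reproducible summits in coding bases, which are 13.3% of the gene; 0 of 25 were there where 3.33 would be expected, too few to exclude chance (two-sided exact binomial p = 0.0683). If extra copies lifted weak sites too, pooled peaks should be dense in the coding bases of shn. They were 3.23 times as dense there as in those of other genes (1.39 to 6.36). The whole interval lies on the denser side, as extra copies would give. Its lower bound fell short of the margin set for this test after results had been seen, and binding is not excluded by it. Pooled summits numbered 9 to 15 in each 10 kb from 11170001 to 11220000 of 2R, but 0 in the 20 kb before it, which includes the start of the gene. What part of shn the transgene holds is not given in the sources used here.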
